A study of Mus musculus with 15 samples.

How the data were processed

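Macrophages were grown from mouse bone marrow and left untreated (M0), given LPS with interferon-gamma (M1), or given IL-4 with IL-13 (M2), and M2 cells were also given nutlin-3a or 10058F4. Each of 15 samples, 3 per group, was read on 1 one-colour array from biotin-labelled cRNA made from total RNA, per the labels' protocols. The authors' deposited values are log2 expression per probe set, made with RMA per the submitters' processing notes; the log base was taken from the values, and the RMA version is not given in the sources used here. RMA corrects background within each array and forces the arrays to one distribution of intensities, so a shift of most genes in one direction would be hidden or turned into shifts of others. Groups and replicate numbers came from the sample titles.

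The table held 45101 probe sets, of which 64 were controls. The platform annotation named 1 gene for 34945 probe sets, several for 932 and none for 9160, which are unnamed here, and 34741 gene IDs were found in the RefSeq table of GRCm38.p6, used for symbols only. Each of 18193 genes was represented by the probe set with the highest mean over 15 arrays among those naming that gene alone. A gene was tested if its value lay above the array's 40th percentile on at least 3 arrays, which left 13703 genes and took out 4490. Trp53, Bax, Isg15 and Ccnb1 were among the genes not analysed here for want of a probe set with that name.

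The comparisons were M1 with M0, M2 with M0, M1 with M2, each agent with M2, and nutlin-3a with 10058F4. Each was a contrast of limma's linear model (lmFit and eBayes) on all 15 arrays with 5 group means, 10 residual and 3.86 prior degrees of freedom, adjusted by Benjamini-Hochberg within the comparison and called at an adjusted p under 0.05. Of 28 gene lists, 27 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over 162 tests. Of the 519 list members 480 had a probe set. Of 68 list calls, 9 held with an estimated correlation: M2 markers in M2 against M0 and M1 against M2, M1 markers and inflammatory chemokines in M1 against M0 and M1 against M2, p53 targets with nutlin-3a against M2 and against 10058F4, and ATF4 genes with nutlin-3a. Some lists share members, such as M1 markers and chemokines.

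Named genes were, for each comparison, Trp53, Mdm2, Cdkn1a and Myc; the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap (5 and 5 for M1 against M2 and for the agents against each other); and up to 4 called members of each list with the largest change, or, where fewer than 2 were called, those with the smallest p. Clone and model names were not named.

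Replicate numbers 1 to 3 recur in all groups, but the sample titles do not say what a number shares. Same-numbered arrays' deviations from their group means correlated, across genes, with r of 0.23 to 0.42 for M2 and M0, 0.34 to 0.38 for nutlin-3a and M2, 0.31 to 0.37 for 10058F4 and M2 and 0.34 to 0.41 for the agents, all above the limit of 0.1 for pairing, so the replicate block is given beside those results where it changes a call.

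For the overlap of the agents and for the genes raised in M2 cells, 100 unchanged groups were simulated against the same M2 arrays, and 10000 random gene lists matched on mean expression were drawn. RNA integrity was read from the 3' and 5' probe sets of beta-actin and Gapdh with exact permutation tests. Alternatives were other filters, the mean of all probe sets or only probe sets specific by suffix, repeated quantile normalization, centring on the median, 6 arrays alone, trended and robust eBayes, array weights, the replicate block, an estimated correlation and each array left out.

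The test was tried on simulated data for nutlin-3a against M2 over 13703 genes, 50 changed per size. It recovered 42% of them at 1.25-fold, 84% at 1.5, 98% at 2 and 100% at 4-fold, with 9 false among 171 calls. Of 100 unchanged lists 2 had p under 0.05, without the correlation of real lists. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.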

Results

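Gene expression was measured in macrophages grown from mouse bone marrow with M-CSF, the growth factor that drives macrophage differentiation, over 7 days. Total RNA from 3 samples in each of 5 groups was hybridised to 15 one-colour arrays. M0 cells were left untreated. M1 cells received LPS, a component of the outer membrane of Gram-negative bacteria, together with interferon-gamma. M2 cells received the cytokines IL-4 and IL-13. The remaining groups were M2 cells given nutlin-3a, which keeps MDM2 from binding p53 and so activates p53, and M2 cells given 10058F4, which blocks the pairing of MYC with its partner MAX. Doses, times and the vehicle of the agents are not given in the sources used here. The labels call the samples biological replicates without saying whether they came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. The series title places p53 at the centre of the study, and Trp53 itself was not analysed here.

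Values are log2 expression after RMA, the authors' normalization, and a log2 difference of 1 is a 2-fold change. Having 3 arrays per group limits the precision of each value. Within each group, arrays correlated with r between 0.989 and 0.997 across probe sets, which are not independent replicates, and M1 replicate 2 had the lowest values. The 3' minus 5' difference of the beta-actin control probe sets, a sign of RNA integrity, was 0.351 ± 0.0543 (SD, n = 3) in M0 and 0.178 ± 0.0444 in M1. It was 0.382 ± 0.0302 in M2, 0.453 ± 0.0346 with nutlin-3a and 0.489 ± 0.025 with 10058F4. For Gapdh it was -0.162 ± 0.0347 in M1 and between -0.284 and -0.272 in the other groups. Of 18193 genes with a probe set of their own, 13703 passed the filter on low values and were tested. Group means under the filter's percentile are not shown to be above background, so differences from them, such as those of Ptgs2 (3.89 in M0), Il6 (2.90), Arg1 (3.56) and Rrm2 (3.09 in M1), are not exact sizes. Errors given for log2 differences are standard errors (SE) of the limma fit, and those given for levels are SDs over 3 arrays.

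M1 cells were compared with M0 cells to find the response to LPS and interferon-gamma. The T cell attracting chemokine Cxcl9 was 395-fold higher in M1 cells (log2 difference 8.63, SE 0.20, adjusted p = 1.4e-13). Ptgs2, the inducible enzyme of prostaglandin synthesis, was also higher (8.58, SE 0.17), as was the inflammatory cytokine Il6 (7.59, SE 0.14). Mrc1, the mannose receptor, fell by 6.09 on the log2 scale (SE 0.27, adjusted p = 7e-11). Rrm2, a subunit of the enzyme that makes deoxynucleotides, had a log2 difference of -5.60 (SE 0.40, adjusted p = 1.5e-08).

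Other large rises in M1 cells were those of the chemokines Cxcl11 (7.85, SE 0.35) and Ccl12 (7.83, SE 0.27), the signalling inhibitor Socs3 (6.93, SE 0.11) and the interferon-induced GTPases Gbp2b (6.72, SE 0.12) and Iigp1 (6.69, SE 0.36). Clic5 (7.78, SE 0.09) and Slfn4 (7.23, SE 0.32) rose as well. Large falls were those of Cd28 (-6.46, SE 0.12), Mamdc2 (-5.66, SE 0.37), the sodium and proton exchangers Slc9a9 (-5.54, SE 0.16) and Slc9a7 (-5.17, SE 0.09), the glycan-branching enzyme Gcnt1 (-5.47, SE 0.17), the prostaglandin-degrading enzyme Hpgd (-5.42, SE 0.19), Rgs18 (-5.12, SE 0.16) and Rnf180 (-5.03, SE 0.12). The p53 target and p53 inhibitor Mdm2 rose by 1.84 (SE 0.09, adjusted p = 2.8e-10). Cdkn1a, the cell cycle inhibitor p21, rose by 2.27 (SE 0.06, adjusted p = 1.2e-12), and Myc had a log2 difference of -0.77 (SE 0.15, adjusted p = 4e-04).

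Gene lists were fixed before the data were examined, and list medians are medians of the members' log2 differences. Of the genes known to answer LPS and interferon-gamma, 27 of 29 rose and 1 fell (27 and 1 adjusted over the list alone). The M1 marker list median was 4.34 (camera adjusted p = 1.78e-15, adjusted p = 0.0145 with an estimated correlation). Among inflammatory chemokines, 13 of 15 rose and 2 fell (13 and 2 adjusted over the list alone), with Cxcl9 and Cxcl11 leading. The chemokine list median was 4.57 (camera adjusted p = 2.51e-06, adjusted p = 0.0101 with an estimated correlation). Type I interferon-stimulated genes rose together: 22 of 22 rose (22 adjusted over the list alone), including Oasl1 (5.93, SE 0.16) and Mx1 (5.74, SE 0.20). The interferon-stimulated list median was 3.05 (camera adjusted p = 7.59e-14, adjusted p = 0.295 with an estimated correlation). In the glycolysis and hypoxia list 19 of 20 rose (19 and 1 lower adjusted over the list alone), among them the lactate exporter Slc16a3 (3.28, SE 0.13) and the glycolysis activator Pfkfb3 (2.94, SE 0.11). The glycolysis and hypoxia list median was 1.59 (camera adjusted p = 2.51e-08, adjusted p = 0.221 with an estimated correlation). MHC class I presentation genes, which show peptides to cytotoxic T cells, followed: 12 of 12 rose (12 adjusted over the list alone), with the transactivator Nlrc5 at 3.30 (SE 0.15) and the peptide transporter Tap1 at 3.19 (SE 0.11). The MHC class I list median was 1.51 (camera adjusted p = 1.34e-06, adjusted p = 0.314 with an estimated correlation). Immediate early genes were also higher: 9 of 14 rose (9 adjusted over the list alone), led by the phosphatase Dusp1 (3.01, SE 0.13). The immediate early list median was 0.68 (camera adjusted p = 0.000335, adjusted p = 0.16 with an estimated correlation). For the ATF4 and amino acid response, 16 of 24 rose and 3 fell (16 and 3 adjusted over the list alone), with the serine synthesis enzyme Psat1 at 3.38 (SE 0.25). The ATF4 list median was 0.50 (camera adjusted p = 0.00436, adjusted p = 0.174 with an estimated correlation).

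Lists of cell division and metabolic genes were called lower in M1 cells at the preset correlation. In the mitosis list 2 of 26 rose and 23 fell (2 and 23 adjusted over the list alone), including Ube2c (-4.25, SE 0.33), Ccnb2 (-3.98, SE 0.34) and Mki67 (-3.92, SE 0.24). The mitosis list median was -2.43 (camera adjusted p = 0.000104, adjusted p = 0.57 with an estimated correlation). In DNA replication 1 of 24 rose and 20 fell (1 and 20 adjusted over the list alone), with Rrm2 and the helicase subunit Mcm6 (-3.37, SE 0.40) among the falls. The DNA replication list median was -1.42 (camera adjusted p = 0.000605, adjusted p = 0.602 with an estimated correlation). For MYC targets and ribosome biogenesis, 4 of 33 rose and 25 fell (4 and 25 adjusted over the list alone). The MYC target list median was -0.79 (camera adjusted p = 0.00066, adjusted p = 0.5 with an estimated correlation). One of the rises was the cyclin Ccnd2 (4.86, SE 0.24), and the transferrin receptor Tfrc was at -2.17 (SE 0.20). Cholesterol synthesis enzymes fell in number: 14 of 15 fell (14 adjusted over the list alone), with Idi1 at -3.11 (SE 0.11) and Sqle at -2.40 (SE 0.16). The cholesterol synthesis list median was -1.40 (camera adjusted p = 7.3e-05, adjusted p = 0.417 with an estimated correlation). Among LXR targets and fatty acid synthesis genes, 2 of 17 rose and 14 fell (2 and 14 adjusted over the list alone), with the desaturase Fads1 at -2.56 (SE 0.15). The LXR target list median was -0.61 (camera adjusted p = 0.03, adjusted p = 0.335 with an estimated correlation). In fatty acid oxidation 2 of 17 rose and 13 fell (2 and 13 adjusted over the list alone), with Hadh at -2.84 (SE 0.10). The fatty acid oxidation list median was -0.56 (camera adjusted p = 0.0101, adjusted p = 0.39 with an estimated correlation). Lysosomal genes were lower: 16 of 21 fell (16 and 1 higher adjusted over the list alone), with the glycosidases Gusb (-1.99, SE 0.07) and Hexa (-1.48, SE 0.06). The lysosome list median was -0.55 (camera adjusted p = 0.00066, adjusted p = 0.461 with an estimated correlation). With arrays centred on their median, 5 lysosomal genes were higher and 11 lower, and the medians were -0.228 for this list, -0.237 for fatty acid oxidation, -0.287 for LXR targets and -0.464 for MYC targets.

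Of the dendritic cell markers, 5 of 8 rose (6 adjusted over the list alone), among them the chemokine receptors Xcr1 (2.50, SE 0.32) and Ccr7 (1.59, SE 0.19). The dendritic cell list median was 0.57 (camera adjusted p = 0.0317, adjusted p = 0.339 with an estimated correlation). That call ended with arrays centred on their median (adjusted p = 0.0975) and without M1 replicate 3 (adjusted p = 0.0573), with 0.0138 to 0.0975 over 11 other settings. Of the T and NK cell markers 5 of 6 rose (5 adjusted over the list alone), with Ncr1 at 0.59 (SE 0.09), and the list was not called. The T and NK cell list median was 0.36 (camera adjusted p = 0.113). B cell markers (3 of 6 rose and 1 fell, 3 and 1 adjusted over the list alone; camera adjusted p = 0.417), neutrophil markers (5 of 9 rose and 2 fell, 5 and 2 adjusted over the list alone; camera adjusted p = 0.534) and mast cell and basophil markers (3 of 5 rose, 3 adjusted over the list alone; camera adjusted p = 0.213) were not called. Nor were stromal markers (1 of 8 rose, 0 adjusted over the list alone; camera adjusted p = 0.824; median -0.15, and 0.18 with arrays centred on their median). The only measured erythroid marker, Klf1, differed by 0.33 (adjusted p = 0.058; 0.0375 without M0 replicate 3 and 0.00858 without M1 replicate 2, with 0.00211 to 0.224 over 15 other settings). Macrophage identity genes went both ways: 5 of 12 rose and 5 fell (5 and 5 adjusted over the list alone), with the transcription factor Cebpa at -2.84 (SE 0.14) and the Fc receptor Fcgr1 at 1.98 (SE 0.14), and no call of the list (camera adjusted p = 0.904).

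The remaining lists were not called in M1 against M0 cells. In the M2 marker list 10 of 25 rose and 10 fell (10 and 10 adjusted over the list alone; camera adjusted p = 0.85), with Mrc1 lower and the arginine transporter Slc7a2 at 4.53 (SE 0.16). In the p53 target list 10 of 26 rose and 11 fell (10 and 11 adjusted over the list alone; camera adjusted p = 0.853), with Sesn1 at -3.89 (SE 0.06) and Fas at 2.91 (SE 0.15). NRF2 targets, which counter oxidative stress, were mixed: 8 of 14 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.251), with Hmox1 at 2.28 (SE 0.17). For the unfolded protein response, 4 of 17 rose and 10 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.422), and the median changed from -0.31 to 0.017 with arrays centred. MHC class II genes were split: 2 of 9 rose and 3 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.752), and the median changed from -0.25 to 0.08 with arrays centred. In the TCA cycle and oxidative phosphorylation list 3 of 25 rose and 17 fell (3 and 17 adjusted over the list alone), with fumarase Fh1 at -1.78 (SE 0.10). The oxidative phosphorylation list median was -0.25 (camera adjusted p = 0.0522). The median became 0.078 with arrays centred, and the list was called without M0 replicate 1 (adjusted p = 0.0347), M0 replicate 3 (adjusted p = 0.0466) or M1 replicate 1 (adjusted p = 0.048) and with no filter on low values (adjusted p = 0.00648), with 0.00648 to 0.581 over 11 other settings.

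In M1 against M0 cells, 4601 genes were higher and 5362 lower (limma, adjusted p under 0.05), of which 783 and 1737 by at least 2-fold. The arrays of the groups did not overlap for 9766 of all tested genes (71.3%), against 10% expected by chance. Centring each array on its median moved the median of all genes from -0.005 to 0.321 and gave 7619 higher and 3505 lower (68.5% higher, against 46.2%). By at least 2-fold, centring gave 1252 higher and 1066 lower, the reverse order. Repeating the quantile normalization gave 5185 and 4488 (920 and 1391 by 2-fold), and a stricter filter lowered the higher calls to 2962. Of 6217 genes with several probe sets, 681 had probe sets called both ways. The beta-actin 3' minus 5' difference was lower by 0.173 in M1 than in M0 and the Gapdh difference higher by 0.111 (exact two-sided permutation p = 0.1 for each, the smallest p that 3 against 3 arrays allow).

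M2 cells were compared with M0 cells to find the response to IL-4 and IL-13. Arg1, the enzyme that splits arginine into ornithine and urea, was higher (log2 difference 6.81, SE 0.66, adjusted p = 2.7e-06). The secreted M2 proteins Retnla and Chil3 rose by 5.21 (SE 0.18) and 4.44 (SE 0.19), and the PD-1 ligand Pdcd1lg2 by 4.97 (SE 0.09). The iron exporter Slc40a1 had a log2 difference of -3.59 (SE 0.30, adjusted p = 7.3e-07), and the interferon-induced Ifit3 of -2.32 (SE 0.20, adjusted p = 1.1e-06). Myc rose by 0.84 (SE 0.15, adjusted p = 0.00075) and Cdkn1a by 1.35 (SE 0.06, adjusted p = 2.7e-09). Mdm2 was 9.43 ± 0.05 in M0 and 9.19 ± 0.11 (SD, n = 3) in M2 cells, a difference that missed the threshold (-0.25, adjusted p = 0.056) and passed it with the replicate number as a block (adjusted p = 0.0381) and without M2 replicate 3 (adjusted p = 0.0364; 0.0113 to 0.373 over 16 other settings).

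Further rises in M2 cells were those of Tmem26 (5.07, SE 0.17), the Ras activator Rasgrp1 (5.05, SE 0.17), the cytokine signalling inhibitor Socs2 (4.42, SE 0.13), Plekhf1 (3.92, SE 0.17), Slc7a2 (3.83, SE 0.16) and the thrombin receptor F2r (3.78, SE 0.21). Further falls were those of Ifit1bl1 (-3.01, SE 0.19), the phosphatase Ptpn22 (-2.91, SE 0.14), the complement receptor C5ar1 (-2.46, SE 0.13), Arhgap18 (-2.37, SE 0.18), Sgms2 (-2.34, SE 0.18), Thbs1 (-2.30, SE 0.25), Zfand4 (-2.05, SE 0.18) and Nfkbiz (-2.03, SE 0.21).

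The M2 marker list was the one whose call held with an estimated correlation in M2 against M0 cells. There 21 of 25 rose (21 and 1 lower adjusted over the list alone). The M2 marker list median was 2.03 (camera adjusted p = 5.51e-22, adjusted p = 0.000276 with an estimated correlation). Cholesterol synthesis genes were higher: 13 of 15 rose (14 adjusted over the list alone), with Mvd (1.29, SE 0.14), Cyp51 (1.29, SE 0.11) and Idi1 (1.22, SE 0.11). The cholesterol synthesis list median was 0.79 (camera adjusted p = 5.42e-10, adjusted p = 0.247 with an estimated correlation). For MYC targets and ribosome biogenesis, 17 of 33 rose (19 adjusted over the list alone), including Tfrc (1.30, SE 0.20) and Nolc1 (0.88, SE 0.12). The MYC target list median was 0.24 (camera adjusted p = 6.31e-07, adjusted p = 0.314 with an estimated correlation). In the unfolded protein response 8 of 17 rose and 2 fell (10 and 2 adjusted over the list alone), with the disulfide isomerase Pdia4 at 1.83 (SE 0.10). The unfolded protein list median was 0.23 (camera adjusted p = 0.00133, adjusted p = 0.314 with an estimated correlation). Type I interferon-stimulated genes were lower: 17 of 22 fell (17 and 1 higher adjusted over the list alone), with Cmpk2 (-1.95, SE 0.15) and Ifit1 (-1.84, SE 0.18) beside Ifit3. The interferon-stimulated list median was -0.87 (camera adjusted p = 9.68e-08, adjusted p = 0.395 with an estimated correlation). NRF2 targets were also lower: 10 of 14 fell (10 adjusted over the list alone), with Hmox1 at -1.29 (SE 0.17) and Gsr at -1.26 (SE 0.07). The NRF2 target list median was -0.53 (camera adjusted p = 5.33e-05, adjusted p = 0.314 with an estimated correlation). In DNA replication 6 of 24 fell (5 adjusted over the list alone), with Cdc6 at -1.51 (SE 0.29) and Cdt1 at -0.70 (SE 0.08). The DNA replication list median was -0.44 (camera adjusted p = 0.00429, adjusted p = 0.65 with an estimated correlation). This call ended without M0 replicate 2 (adjusted p = 0.0998, with 2.54e-08 to 0.0998 over 11 other settings).

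Among dendritic cell markers 1 of 8 rose (1 adjusted over the list alone), the transcription factor Batf3 (2.90, SE 0.11). The dendritic cell list median was 0.24 (camera adjusted p = 0.0353, adjusted p = 0.342 with an estimated correlation). That call ended without M0 replicate 2 (adjusted p = 0.0923), with no filter on low values (adjusted p = 0.0662), with the mean of all probe sets (adjusted p = 0.134) and with arrays centred (adjusted p = 0.0834), with 0.0148 to 0.134 over 11 other settings. In the macrophage identity list 1 of 12 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.446; median -0.051, and 0.033 with arrays centred), with the engulfment receptor Mertk at -1.43 (SE 0.09). The other marker lists had camera adjusted p from 0.265 (mast cells and basophils) to 0.765 (neutrophils, of which 1 of 9 rose and 2 fell, 1 and 2 adjusted over the list alone).

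In M2 against M0 cells M1 markers were not called and went both ways: 4 of 29 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.183), with Cd86 at 2.16 (SE 0.15) and Fpr2 at -1.63 (SE 0.21). Of the p53 targets 4 of 26 rose and 11 fell (5 and 12 adjusted over the list alone; camera adjusted p = 0.198), with Pmaip1 at -1.65 (SE 0.09). In glycolysis and hypoxia 3 of 20 rose and 10 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.417), with the growth factor Vegfa at -1.45 (SE 0.24). For fatty acid oxidation 1 of 17 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.752; median -0.008, and 0.076 with arrays centred), with the coactivator Ppargc1b at 1.64 (SE 0.09). Immediate early genes (5 of 14 rose and 2 fell, 6 and 3 adjusted over the list alone; camera adjusted p = 0.0703) were called without M0 replicate 3 (adjusted p = 0.0493) or M2 replicate 2 (adjusted p = 0.045), with 0.045 to 0.162 over 11 other settings. ATF4 genes (7 of 24 rose, 6 adjusted over the list alone; camera adjusted p = 0.0725) were called without M2 replicate 1 (adjusted p = 0.0376, with 0.0376 to 0.191 over 11 other settings). Of 26 mitosis genes 0 passed limma's test and 3 had an unadjusted p under 0.05 (median -0.017, camera adjusted p = 0.722); the median was 0.068 with arrays centred, and the list was called higher without M0 replicate 2 (adjusted p = 0.0243, with 0.0243 to 0.916 over 11 other settings). Chemokines, LXR targets, oxidative phosphorylation, MHC class I, MHC class II and lysosome lists had camera adjusted p between 0.251 and 0.71.

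In M2 against M0 cells 1735 genes were higher and 2518 lower, of which 200 and 219 by at least 2-fold, and 6470 of all tested genes (47.2%) had non-overlapping arrays, against 10% by chance. With arrays centred the split was 2801 higher and 1791 lower (61% higher, against 40.8%), and with repeated quantile normalization 2093 and 1974 (51.5%), so the side with more calls depended on the scaling.

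**Figure D1:**
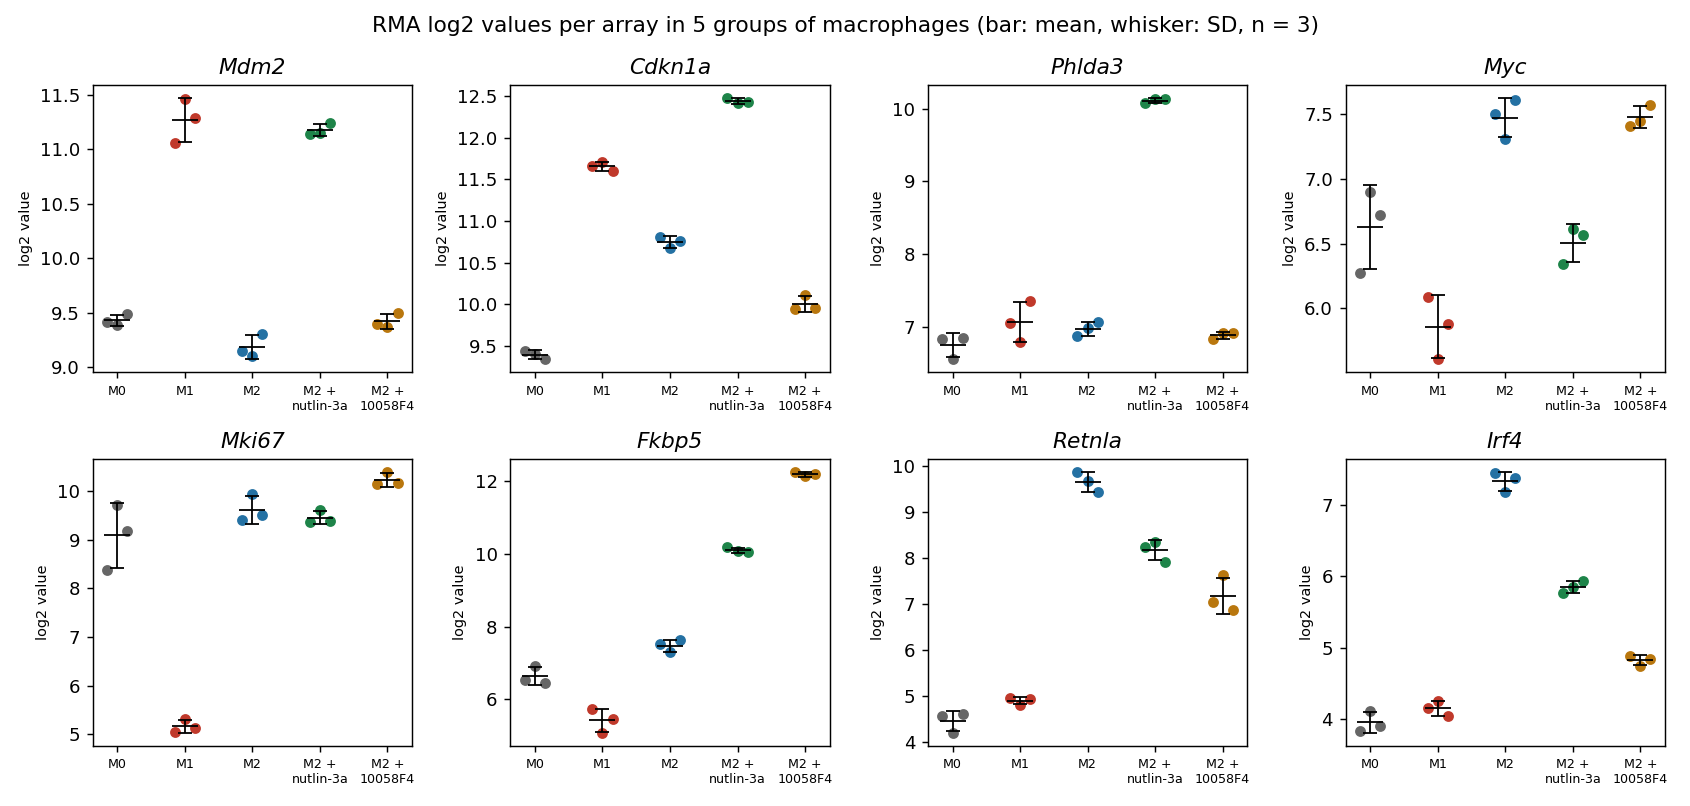
RMA log2 values (y axis) of 8 genes on each of the 15 arrays, by group (x axis), with the mean (bar) and SD (whisker) of 3 arrays; y axes differ and do not start at 0. Mdm2 was 9.19 ± 0.11 in M2 cells and 11.18 ± 0.05 with nutlin-3a, and Fkbp5 was higher with both agents than in M2 cells.

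M1 and M2 cells were compared directly as the opposed polarized states. Cxcl9 (8.95, SE 0.20), Slfn4 (8.02, SE 0.32), Cxcl11 (7.88, SE 0.35), Ptgs2 (7.71, SE 0.17) and Il6 (7.62, SE 0.14) were higher in M1 cells. Mrc1 (-8.12, SE 0.27), the transcription factor Egr2 (-6.89, SE 0.10), the sialyltransferase St6gal1 (-6.02, SE 0.11), Chil3 (-5.96, SE 0.19) and Rnase4 (-5.65, SE 0.16) were lower, that is, higher in M2 cells. Mdm2 was higher in M1 cells by 2.08 (SE 0.09, adjusted p = 6.9e-11) and Cdkn1a by 0.91 (SE 0.06, adjusted p = 1.3e-08). Myc was lower in M1 cells (-1.61, SE 0.15, adjusted p = 2.9e-07).

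By list, higher in M1 than in M2 cells were M1 markers, of which 28 of 29 were higher and 1 was lower (28 and 1 adjusted over the list alone). The M1 marker list median was 4.44 (camera adjusted p = 3.67e-18, adjusted p = 0.0101 with an estimated correlation). Of inflammatory chemokines 13 of 15 were higher and 2 were lower (13 and 2 adjusted over the list alone). The chemokine list median was 3.80 (camera adjusted p = 1.95e-06, adjusted p = 0.0101 with an estimated correlation). Of type I interferon-stimulated genes 22 of 22 were higher (22 adjusted over the list alone), such as Mx1 (7.30, SE 0.20). The interferon-stimulated list median was 3.96 (camera adjusted p = 1.62e-16, adjusted p = 0.229 with an estimated correlation). Of glycolysis and hypoxia genes 20 of 20 were higher (20 adjusted over the list alone), such as Pfkfb3 (4.18, SE 0.11) and Bnip3 (3.08, SE 0.12). The glycolysis and hypoxia list median was 1.84 (camera adjusted p = 4.15e-10, adjusted p = 0.16 with an estimated correlation). Of MHC class I genes 12 of 12 were higher (12 adjusted over the list alone). The MHC class I list median was 1.41 (camera adjusted p = 4.62e-07, adjusted p = 0.314 with an estimated correlation). NRF2 targets, with Hmox1 at 3.57 (SE 0.17), divided so that 9 of 14 were higher and 3 were lower (9 and 3 adjusted over the list alone). The NRF2 target list median was 0.95 (camera adjusted p = 0.00695, adjusted p = 0.5 with an estimated correlation). Of immediate early genes 9 of 14 were higher and 1 was lower (9 and 1 adjusted over the list alone), such as Dusp1 (3.33, SE 0.13). The immediate early list median was 0.33 (camera adjusted p = 0.0104, adjusted p = 0.314 with an estimated correlation). In the ATF4 list 11 of 24 were higher and 5 were lower (11 and 5 adjusted over the list alone), with Psat1 at 3.72 (SE 0.25) and Atf5 at -1.59 (SE 0.12). The ATF4 list median was 0.14 (camera adjusted p = 0.037, adjusted p = 0.314 with an estimated correlation).

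Lower in M1 than in M2 cells were M2 markers, of which 4 of 25 were higher and 20 were lower (4 and 20 adjusted over the list alone). The M2 marker list median was -2.72 (camera adjusted p = 4.23e-06, adjusted p = 0.0145 with an estimated correlation). In cholesterol synthesis 14 of 15 were lower (14 adjusted over the list alone), Idi1 by the most (-4.33, SE 0.11). The cholesterol synthesis list median was -2.22 (camera adjusted p = 4.18e-07, adjusted p = 0.314 with an estimated correlation). MYC targets followed, where 3 of 33 were higher and 27 were lower (3 and 27 adjusted over the list alone), Srm at -2.22 (SE 0.13). The MYC target list median was -1.10 (camera adjusted p = 1.68e-06, adjusted p = 0.335 with an estimated correlation). Of mitosis genes 1 of 26 was higher and 23 were lower (1 and 23 adjusted over the list alone), Mki67 at -4.45 (SE 0.24). The mitosis list median was -2.38 (camera adjusted p = 3.08e-05, adjusted p = 0.554 with an estimated correlation). Of DNA replication genes 2 of 24 were higher and 16 were lower (2 and 16 adjusted over the list alone). The DNA replication list median was -0.98 (camera adjusted p = 0.0128, adjusted p = 0.685 with an estimated correlation). Fatty acid oxidation, with Hadh at -2.40 (SE 0.10), had the same sign: 3 of 17 were higher and 13 were lower (3 and 13 adjusted over the list alone). The fatty acid oxidation list median was -0.66 (camera adjusted p = 0.00432, adjusted p = 0.335 with an estimated correlation). Of lysosomal genes 2 of 21 were higher and 16 were lower (2 and 16 adjusted over the list alone), Gusb at -1.75 (SE 0.07). The lysosome list median was -0.48 (camera adjusted p = 0.0036, adjusted p = 0.514 with an estimated correlation). In the unfolded protein response 2 of 17 were higher and 10 were lower (2 and 10 adjusted over the list alone), Pdia4 at -2.19 (SE 0.10). The unfolded protein list median was -0.45 (camera adjusted p = 0.0223, adjusted p = 0.418 with an estimated correlation). In oxidative phosphorylation 1 of 25 was higher and 16 were lower (1 and 16 adjusted over the list alone), Fh1 at -1.83 (SE 0.10). The oxidative phosphorylation list median was -0.28 (camera adjusted p = 0.0106, adjusted p = 0.554 with an estimated correlation).

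Calls that ended in a setting between M1 and M2 cells were those of ATF4 (adjusted p = 0.0625 with no filter, 0.138 with the mean of all probe sets, 0.0684 centred, 0.0543 with the 6 arrays alone; 0.0226 to 0.138 over 11 other settings), DNA replication (adjusted p = 0.0597 with the mean of all probe sets; 0.000655 to 0.0597 over 11 other settings), the unfolded protein response (adjusted p = 0.0752 and 0.0527 with the mean of all probe sets and centred; 0.00288 to 0.0752 over 11 other settings) and oxidative phosphorylation (adjusted p = 0.0602 and 0.143 likewise, with 7 genes higher, 9 lower and a median of -0.033 when centred; 0.000994 to 0.143 over 11 other settings). LXR targets and fatty acid synthesis (3 of 17 were higher and 11 were lower, 3 and 11 adjusted over the list alone; median -0.47, camera adjusted p = 0.133) were called with no filter on low values (adjusted p = 0.037, with 0.037 to 0.183 over 11 other settings). The p53 list (10 of 26 were higher and 11 were lower, 10 and 12 adjusted over the list alone; camera adjusted p = 0.775) had a median of -0.11, and of 0.133 with arrays centred. MHC class II genes (median -0.17, and 0.07 centred), stromal markers (median -0.15, and 0.088 centred), macrophage identity and the other cell type lists had camera adjusted p from 0.242 to 0.897.

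Between M1 and M2 cells 3855 genes were higher and 5005 lower in M1 cells (43.5% higher), of which 887 and 1526 by at least 2-fold. Centring gave 6896 and 3644 (65.4%, with a median of all genes of 0.237), of which 1154 and 1047 by 2-fold. The beta-actin 3' minus 5' difference was lower by 0.204 in M1 than in M2 and the Gapdh difference higher by 0.122 (exact two-sided permutation p = 0.1 each, the smallest possible).

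M2 cells with nutlin-3a were compared with M2 cells to find the effect of p53 activation. Mdm2 rose 3.97-fold, from 9.19 ± 0.11 to 11.18 ± 0.05 (SD, n = 3; log2 difference 1.99, SE 0.09, adjusted p = 7.7e-09). Cdkn1a rose by 1.7 (SE 0.06, adjusted p = 1.1e-09), and Phlda3, a p53 target that restrains AKT signalling, was 8.75-fold higher (3.13, SE 0.12, adjusted p = 9.6e-10). The cyclin Ccna2 had a log2 difference of -2.07 (SE 0.31, adjusted p = 0.00047), and Myc fell from 7.47 ± 0.15 to 6.51 ± 0.14 (-0.96, SE 0.15, adjusted p = 0.00079).

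Other genes that rose with nutlin-3a were Psrc1 (2.91, SE 0.14), the RNA-binding protein Zmat3 (2.54, SE 0.08), Trp53inp1 (2.20, SE 0.11), the thiamine transporter Slc19a2 (2.44, SE 0.08), the MYC-neighbouring noncoding RNA Pvt1 (2.10, SE 0.13), Ddias (2.07, SE 0.23), the mTOR inhibitor Ddit4 (2.52, SE 0.15), the glucocorticoid receptor cochaperone Fkbp5 (2.63, SE 0.15) and Rgs1 (2.53, SE 0.17). Others that fell were Pbk (-2.07, SE 0.43), Aspm (-2.02, SE 0.33), Anln (-1.98, SE 0.34), Uhrf1 (-1.95, SE 0.37), Cenpf (-1.94, SE 0.34), Rrm2 (-1.86, SE 0.40), Kif20a (-1.83, SE 0.32), Bub1 (-1.79, SE 0.35) and Cep55 (-1.73, SE 0.29), most of which act in cell division.

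Of the p53 targets fixed beforehand, 21 of 26 rose and 2 fell (21 and 2 adjusted over the list alone) with nutlin-3a. The p53 target list median was 1.03 (camera adjusted p = 5.71e-23, adjusted p = 0.00132 with an estimated correlation). In the ATF4 and amino acid response 12 of 24 rose and 1 fell (12 and 1 adjusted over the list alone), with Ddit4, the folate enzyme Mthfd2 (1.34, SE 0.14) and the asparagine synthetase Asns (1.28, SE 0.21). The ATF4 list median was 0.28 (camera adjusted p = 6.12e-08, adjusted p = 0.0101 with an estimated correlation). Mitosis genes fell together: 22 of 26 fell (24 adjusted over the list alone), with Ccna2, Kif20a, Bub1 and Nusap1 (-1.68, SE 0.35). The mitosis list median was -1.10 (camera adjusted p = 5.34e-14, adjusted p = 0.322 with an estimated correlation). Among DNA replication genes 5 of 24 fell (5 adjusted over the list alone), Uhrf1 and Rrm2 the most. The DNA replication list median was -0.33 (camera adjusted p = 2.35e-05, adjusted p = 0.531 with an estimated correlation). Type I interferon-stimulated genes were lower: 8 of 22 fell (11 and 1 higher adjusted over the list alone), with Ifit1 at -1.32 (SE 0.18) and Rsad2 at -1.08 (SE 0.20). The interferon-stimulated list median was -0.36 (camera adjusted p = 4.78e-05, adjusted p = 0.514 with an estimated correlation). Of the M1 markers 3 of 29 rose and 7 fell (3 and 9 adjusted over the list alone), with Cxcl10 at -1.44 (SE 0.21) and the costimulatory ligand Cd80 at 1.42 (SE 0.12). The M1 marker list median was -0.23 (camera adjusted p = 0.0101, adjusted p = 0.418 with an estimated correlation). It was not called with arrays centred (adjusted p = 0.0684, with 0.00283 to 0.0684 over 11 other settings).

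Other list calls with nutlin-3a had camera adjusted p from 0.0353 to 0.0451. NRF2 targets were called higher with Gsr (0.84, SE 0.07) as the member that passed: 1 of 14 rose (1 adjusted over the list alone). The NRF2 target list median was 0.20 (camera adjusted p = 0.0368, adjusted p = 0.554 with an estimated correlation). This call ended without M2 replicate 1 (adjusted p = 0.0692) or nutlin-3a replicate 3 (adjusted p = 0.139), with 0.0105 to 0.139 over 11 other settings. Of cholesterol synthesis genes 2 of 15 rose (2 adjusted over the list alone), with Insig1, an inhibitor of that pathway, at 0.53 (SE 0.09). The cholesterol synthesis list median was 0.15 (camera adjusted p = 0.0451, adjusted p = 0.645 with an estimated correlation). Without M2 replicate 1, M2 replicate 3 or nutlin-3a replicate 2 the adjusted p was 0.0921, 0.14 and 0.16, with 0.00981 to 0.16 over 11 other settings. Of lysosomal genes 4 of 21 rose (6 adjusted over the list alone), with Gla at 0.43 (SE 0.06). The lysosome list median was 0.10 (camera adjusted p = 0.0353, adjusted p = 0.621 with an estimated correlation). The lysosome call ended centred (adjusted p = 0.0807) and without nutlin-3a replicate 2 (adjusted p = 0.0543), with 0.0106 to 0.0807 over 11 other settings. Of MHC class II genes 3 of 9 fell (4 adjusted over the list alone), with H2-DMa at -0.82 (SE 0.13). The MHC class II list median was -0.27 (camera adjusted p = 0.0382, adjusted p = 0.57 with an estimated correlation). That call ended without M2 replicate 1, M2 replicate 3 or nutlin-3a replicate 2 (adjusted p = 0.111, 0.058 and 0.144), with the mean of all probe sets (0.0602), centred (0.119) and with the 6 arrays alone (0.0511), with 0.00998 to 0.144 over 11 other settings.

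M2 markers were not called with nutlin-3a: 4 of 25 rose and 8 fell (6 and 9 adjusted over the list alone; median -0.15, camera adjusted p = 0.0567), with Retnla at -1.49 (SE 0.18), the transcription factor Irf4 at -1.48 (SE 0.09) and the lectin Mgl2 at -1.33 (SE 0.20). They were called lower without M2 replicate 2 (adjusted p = 0.0356) or nutlin-3a replicate 1 (adjusted p = 0.0228), with 0.0228 to 0.253 over 11 other settings. MYC targets and ribosome biogenesis genes were not called either: 2 of 33 rose and 5 fell (3 and 8 adjusted over the list alone; median -0.069, camera adjusted p = 0.124), with Dkc1 at -0.45 (SE 0.08) and the polyamine enzyme Odc1 at 0.44 (SE 0.08). Dendritic cell markers (median -0.13, camera adjusted p = 0.0522; Batf3 -1.01, SE 0.11) were called with the replicate block (adjusted p = 0.0427), without M2 replicate 2 (adjusted p = 0.0264) and with the 6 arrays alone (adjusted p = 0.0428), with 0.0264 to 0.125 over 11 other settings. The unfolded protein response (5 of 17 rose, 5 adjusted over the list alone; median 0.082, camera adjusted p = 0.0725) was called without M2 replicate 2 (adjusted p = 0.0279), with no filter (0.0277) and with the mean of all probe sets (0.0148), with 0.0148 to 0.146 over 11 other settings. MHC class I genes (3 of 12 fell, 3 adjusted over the list alone; median -0.045, camera adjusted p = 0.121) were called lower without M2 replicate 2 (adjusted p = 0.0255) or nutlin-3a replicate 1 (adjusted p = 0.0271), with 0.0255 to 0.336 over 11 other settings. Oxidative phosphorylation (median -0.067, camera adjusted p = 0.195) was called only with arrays centred (adjusted p = 0.0495, with 0.0495 to 0.626 over 11 other settings). The other lists had camera adjusted p from 0.113 (B cell markers) to 0.928 (fatty acid oxidation, median 0.052, and -0.009 centred).

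With nutlin-3a 1310 genes were higher and 802 lower than in M2 cells, of which 75 and 71 by at least 2-fold, and 5328 of all tested genes (38.9%) had non-overlapping arrays (10% by chance). Leaving out 1 array lowered the higher calls to 774 (M2 replicate 1) or 756 (nutlin-3a replicate 2) and the lower calls to 469 (M2 replicate 1), 504 (M2 replicate 3), 462 (nutlin-3a replicate 1) or 495 (nutlin-3a replicate 2). Centred arrays gave 926 higher and 1320 lower (41.2% higher, against 62%), repeated quantile normalization 1104 and 1037 (51.6%), and array weights 2022 and 1280. The beta-actin 3' minus 5' difference was higher by 0.071 with nutlin-3a (exact two-sided permutation p = 0.1, the smallest possible).

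**Figure D2:**
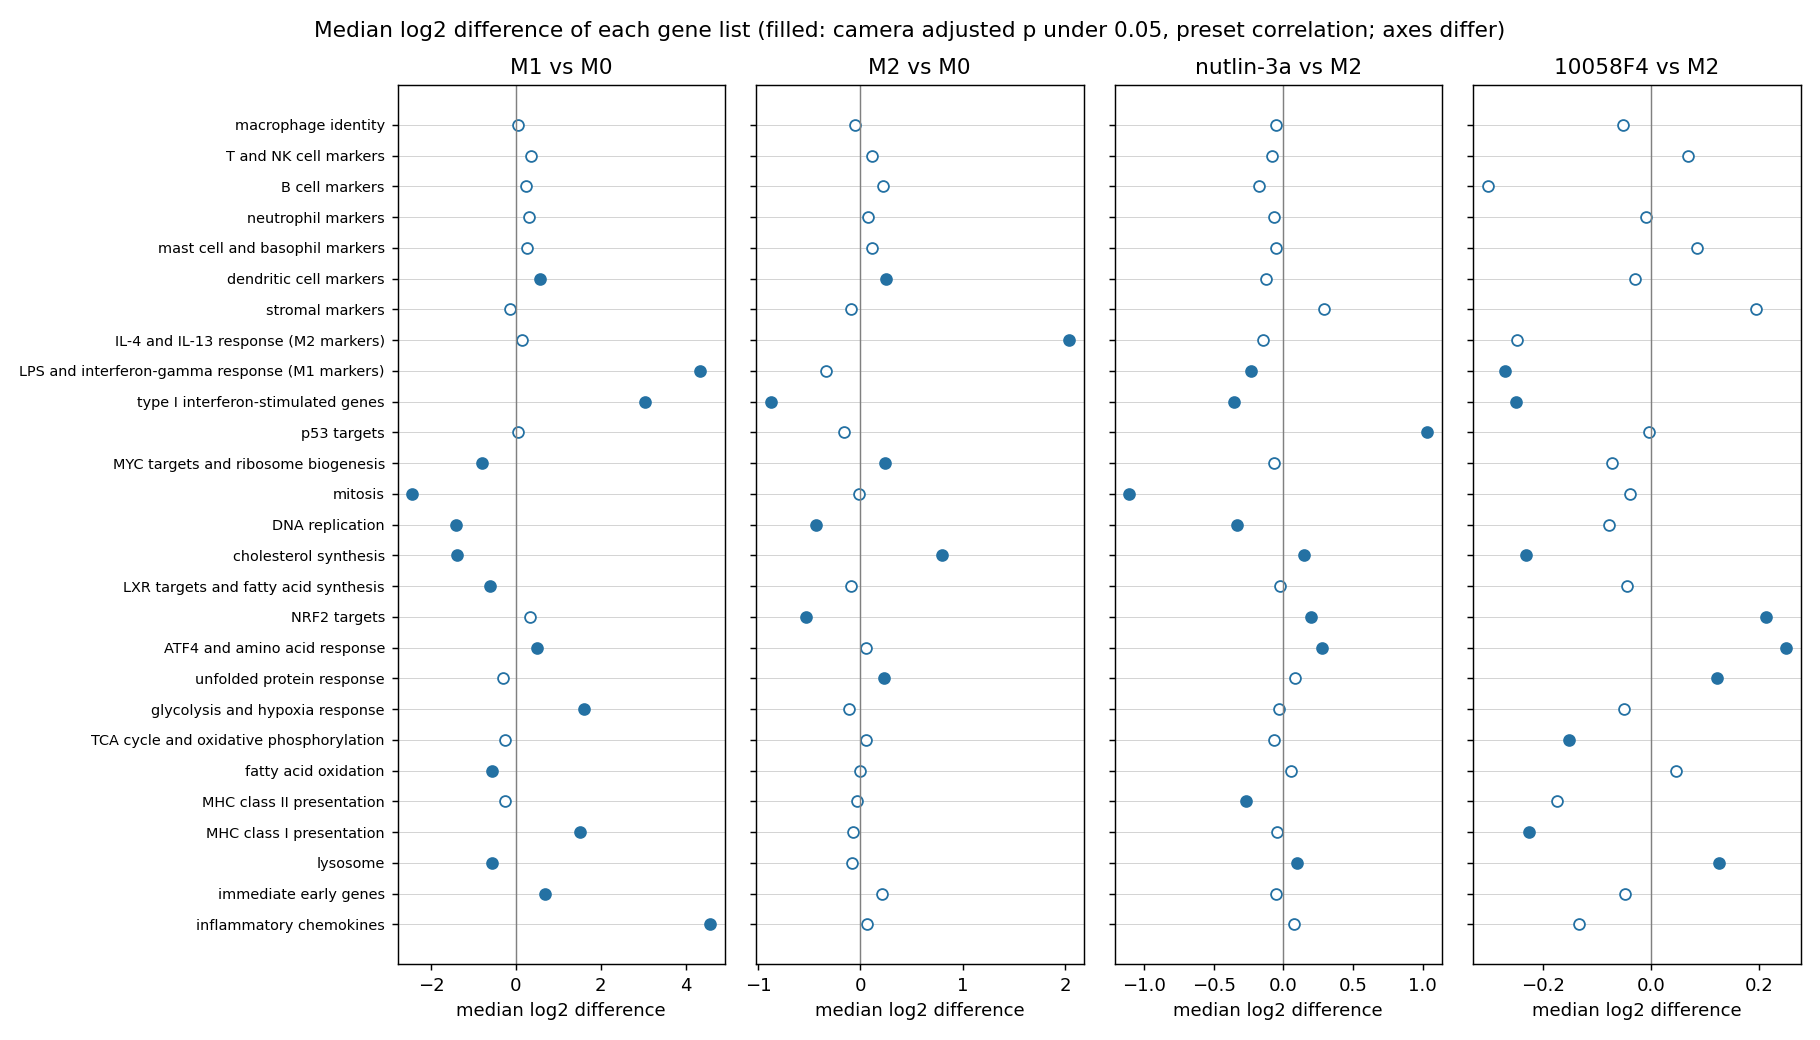
Median log2 difference (x axis, scales differ) of each of 27 gene lists (rows) in 4 comparisons; filled points passed camera at the preset correlation, and of all 68 such calls in 6 comparisons 9 held with an estimated correlation. With nutlin-3a the p53 list had a median of 1.03 and the mitosis list of -1.10, and with 10058F4 these medians were -0.004 and -0.039.

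M2 cells with 10058F4 were compared with M2 cells to find the effect of blocking MYC. Fkbp5 was 26.3-fold higher (log2 difference 4.72, SE 0.15, adjusted p = 1.4e-10), and the circadian regulator Per1 and the glucocorticoid-induced Tsc22d3 rose by 2.44 (SE 0.11) and 2.39 (SE 0.20). Irf4, a transcription factor of the IL-4 response, had a log2 difference of -2.50 (SE 0.09, adjusted p = 6.3e-10), and Retnla of -2.48 (SE 0.18, adjusted p = 3.5e-07). Myc itself was 7.47 ± 0.15 in M2 cells and 7.47 ± 0.08 (SD, n = 3) with 10058F4 (adjusted p = 1). Cdkn1a fell from 10.75 ± 0.07 to 10 ± 0.1 (-0.75, SE 0.06, adjusted p = 2.2e-06), and Mdm2 missed the threshold (0.24, SE 0.09, adjusted p = 0.081). Mdm2 passed it with array weights (adjusted p = 0.01), with the 6 arrays alone (adjusted p = 0.0445) and with trended and robust eBayes, with 0.01 to 0.538 over 16 other settings.

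Other genes that rose with 10058F4 were Rgs1 (3.68, SE 0.17), Dusp1 (2.94, SE 0.13), Ddit4 (2.75, SE 0.15), the AP-1 repressor Jdp2 (2.67, SE 0.11), the zinc transporter family member Slc39a12 (2.43, SE 0.20), the prostaglandin receptor Ptger2 (2.31, SE 0.31) and Abhd15 (2.31, SE 0.16). Others that fell were Hivep3 (-2.37, SE 0.08), Enc1 (-2.36, SE 0.17), Pald1 (-2.14, SE 0.17), the adhesion molecule Icam1 (-2.00, SE 0.07), the lipopeptide receptor Tlr1 (-1.89, SE 0.08), the potassium channel Kcnn4 (-1.87, SE 0.10), F2r (-1.78, SE 0.21) and Rgs2 (-1.77, SE 0.17).

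The MYC target and ribosome biogenesis list was not called with 10058F4: 4 of 33 rose and 2 fell (4 and 2 adjusted over the list alone; median -0.072, camera adjusted p = 0.752), with Odc1 at 1.02 (SE 0.08) and the nucleolar protein Npm1 at 0.35 (SE 0.06). Of 26 mitosis and 24 DNA replication genes 0 passed limma's test, over all genes or adjusted over the list alone, and 1 of each list had an unadjusted p under 0.05 (camera adjusted p = 0.824 and 0.443). Mki67 was at 0.62 (adjusted p = 0.09) and passed the test in 3 of 16 other settings (adjusted p 0.015 to 0.256). The replicate block was 1 of these (adjusted p = 0.0184). Gins1 was at -0.45 (adjusted p = 0.059) and passed with the block (adjusted p = 0.0242) and without 10058F4 replicate 2 (adjusted p = 0.0294; 0.0215 to 0.245 over 16 other settings). The p53 list had 6 of 26 higher and 7 lower (8 and 9 adjusted over the list alone; median -0.004, camera adjusted p = 0.785), with Trp53inp1 at 1.14 (SE 0.11) and Dram1 at -1.04 (SE 0.07). M2 markers were not called: 6 of 25 rose and 11 fell (6 and 13 adjusted over the list alone; median -0.25, camera adjusted p = 0.119), with Irf4 and Retnla lower and Socs2 at 1.72 (SE 0.13).

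No list call with 10058F4 held with an estimated correlation. Of the M1 markers 1 of 29 rose and 13 fell (1 and 14 adjusted over the list alone), with Cxcl10 at -1.76 (SE 0.21), the receptor Tlr2 at -1.61 (SE 0.09) and Cd40 at -1.27 (SE 0.08). The M1 marker list median was -0.27 (camera adjusted p = 1.86e-05, adjusted p = 0.229 with an estimated correlation). Type I interferon-stimulated genes were lower: 7 of 22 fell (7 adjusted over the list alone), with Gbp3 at -0.86 (SE 0.14). The interferon-stimulated list median was -0.25 (camera adjusted p = 0.00332, adjusted p = 0.621 with an estimated correlation). Of MHC class I genes 4 of 12 fell (5 adjusted over the list alone), with the immunoproteasome subunits Psmb10 (-1, SE 0.07) and Psmb9 (-0.76, SE 0.10). The MHC class I list median was -0.23 (camera adjusted p = 0.00429, adjusted p = 0.514 with an estimated correlation). In oxidative phosphorylation 10 of 25 fell (12 adjusted over the list alone), with Sdhb at -0.40 (SE 0.06). The oxidative phosphorylation list median was -0.15 (camera adjusted p = 0.000605, adjusted p = 0.469 with an estimated correlation). Of the ATF4 list 9 of 24 rose and 1 fell (11 and 2 adjusted over the list alone), with Ddit4, Asns (1.06, SE 0.21) and Atf5 (1.04, SE 0.12). The ATF4 list median was 0.25 (camera adjusted p = 0.00342, adjusted p = 0.16 with an estimated correlation). Unfolded protein response genes were higher: 7 of 17 rose (7 adjusted over the list alone), with Dnajb9 at 0.87 (SE 0.06). The unfolded protein list median was 0.12 (camera adjusted p = 0.00228, adjusted p = 0.314 with an estimated correlation). Among NRF2 targets 3 of 14 rose and 1 fell (5 and 1 adjusted over the list alone), with the cystine transporter Slc7a11 at 1.44 (SE 0.22) and Gsr at 1.19 (SE 0.07). The NRF2 target list median was 0.21 (camera adjusted p = 0.0148, adjusted p = 0.514 with an estimated correlation). Of lysosomal genes 7 of 21 rose (7 adjusted over the list alone), with Gla at 0.50 (SE 0.06). The lysosome list median was 0.13 (camera adjusted p = 0.0205, adjusted p = 0.57 with an estimated correlation). Of cholesterol synthesis genes 1 of 15 rose and 3 fell (1 and 3 adjusted over the list alone), with Insig1 the rise (0.37, SE 0.09). The cholesterol synthesis list median was -0.23 (camera adjusted p = 0.0364, adjusted p = 0.635 with an estimated correlation). The cholesterol call ended without M2 replicate 2, 10058F4 replicate 1 or 10058F4 replicate 3 (adjusted p = 0.173, 0.106 and 0.0707) and with the mean of all probe sets (0.0597), with 0.00495 to 0.173 over 11 other settings.

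MHC class II genes (3 of 9 fell, 3 adjusted over the list alone; median -0.17, camera adjusted p = 0.0836), with H2-DMa at -1.25 (SE 0.13), were called lower with the replicate block (adjusted p = 0.0342) and without M2 replicate 2 (adjusted p = 0.0264) or 10058F4 replicate 1 (adjusted p = 0.0278), with 0.0264 to 0.237 over 11 other settings. The remaining lists had camera adjusted p from 0.218 (B cell markers) to 0.984 (immediate early genes, with Dusp1 and Fos, at 1.91, SE 0.17, higher and Klf2, at -1.01, SE 0.14, lower). In macrophage identity 1 of 12 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.348), with Mertk at 2.15 (SE 0.09).

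With 10058F4 1456 genes were higher and 1402 lower than in M2 cells, of which 122 and 108 by at least 2-fold, and 6063 of all tested genes (44.2%) had non-overlapping arrays (10% by chance); array weights gave 2201 and 2110. The beta-actin 3' minus 5' difference was higher by 0.106 with 10058F4 (exact two-sided permutation p = 0.1, the smallest possible).

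The agents were set against each other directly, which leaves the M2 arrays out of the difference. Psrc1 (3.63, SE 0.14), Phlda3 (3.22, SE 0.12), Zmat3 (2.87, SE 0.08), the plasminogen activator Plau (2.71, SE 0.22) and Cdkn1a (2.45, SE 0.06) were higher with nutlin-3a than with 10058F4, as was Mdm2 (1.75, SE 0.09). Sla (-2.19, SE 0.12), Pbk (-2.19, SE 0.43), Fkbp5 (-2.09, SE 0.15), Rrm2 (-2.04, SE 0.40), Anln (-1.99, SE 0.34) and Myc (-0.97, SE 0.15, adjusted p = 0.0011) were lower. Of the p53 targets 20 of 26 were higher (21 adjusted over the list alone) with nutlin-3a. The p53 target list median was 1.09 (camera adjusted p = 1.16e-35, adjusted p = 0.000276 with an estimated correlation). Of mitosis genes 16 of 26 were lower (25 adjusted over the list alone). The mitosis list median was -1.10 (camera adjusted p = 3.92e-18, adjusted p = 0.302 with an estimated correlation). Of DNA replication genes 2 of 24 were lower (4 adjusted over the list alone), Rrm2 by the most. The DNA replication list median was -0.25 (camera adjusted p = 8.58e-05, adjusted p = 0.554 with an estimated correlation).

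Cholesterol synthesis was higher with nutlin-3a: 6 of 15 were called (11 adjusted over the list alone), such as Idi1 (0.52, SE 0.11). The cholesterol synthesis list median was 0.36 (camera adjusted p = 2.74e-07, adjusted p = 0.314 with an estimated correlation). Of M1 markers 9 of 29 were higher (9 adjusted over the list alone), such as Cd80 (1.57, SE 0.12) and Il15 (0.91, SE 0.08). The M1 marker list median was 0.20 (camera adjusted p = 5.33e-05, adjusted p = 0.258 with an estimated correlation). Of ATF4 genes 5 of 24 were higher (11 adjusted over the list alone). The ATF4 list median was 0.20 (camera adjusted p = 0.00142, adjusted p = 0.14 with an estimated correlation). In oxidative phosphorylation 1 of 25 was higher (0 adjusted over the list alone). The oxidative phosphorylation list median was 0.11 (camera adjusted p = 0.00131, adjusted p = 0.5 with an estimated correlation). Of MHC class I genes 2 of 12 were higher (4 adjusted over the list alone), such as Psmb10 (0.54, SE 0.07). The MHC class I list median was 0.18 (camera adjusted p = 0.00695, adjusted p = 0.538 with an estimated correlation). This call ended without nutlin-3a replicate 1 (adjusted p = 0.0723, with 0.000418 to 0.0723 over 11 other settings). In the unfolded protein response 3 of 17 were lower (4 and 1 higher adjusted over the list alone), such as Dnajb9 (-0.46, SE 0.06). The unfolded protein list median was -0.065 (camera adjusted p = 0.0166, adjusted p = 0.408 with an estimated correlation). That call ended without 10058F4 replicate 2 (adjusted p = 0.06) and with the 6 arrays alone (adjusted p = 0.0582), with 0.00351 to 0.06 over 11 other settings. M2 markers were not called (6 of 25 were higher and 4 were lower, 8 and 4 adjusted over the list alone; median 0.10, camera adjusted p = 0.581), with Klf4 at -1.32 (SE 0.14) and Egr2 at 1.04 (SE 0.10). MYC targets (2 of 33 were lower, 2 adjusted over the list alone; median -0.024, camera adjusted p = 0.0658) were called lower without nutlin-3a replicate 2 (adjusted p = 0.0202) or 10058F4 replicate 1 (adjusted p = 0.0231), with 0.0202 to 0.275 over 11 other settings. Type I interferon-stimulated genes (2 of 22 were higher and 2 were lower, 2 and 2 adjusted over the list alone; median -0.064, camera adjusted p = 0.267) were called lower without 10058F4 replicate 2 (adjusted p = 0.0391, with 0.0391 to 0.901 over 11 other settings). The other lists had camera adjusted p from 0.242 to 0.99, and the medians of the macrophage identity (0.004 and -0.049), B cell (0.04 and -0.012), LXR (0.01 and -0.043) and glycolysis (0.005 and -0.048) lists changed sign when arrays were centred.

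Between the agents 581 genes were higher with nutlin-3a and 373 lower, of which 67 and 70 by at least 2-fold (centred arrays 434 and 543, or 44.4% higher against 60.9%; repeated quantile normalization 486 and 471, or 50.8%). Leaving out 1 array gave as few as 339 higher (nutlin-3a replicate 2), 354 (10058F4 replicate 1) and 350 (10058F4 replicate 3), and 245, 221, 213, 233 and 239 lower (nutlin-3a replicates 2 and 3, 10058F4 replicates 1, 2 and 3), while array weights gave 1272 and 772 and the 6 arrays alone 875 and 608.

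Against the same M2 arrays, 815 genes were higher with both agents, 545 were lower with both and 22 went opposite ways. Fkbp5, Rgs1, Ddit4, Jdp2, Tsc22d3 and Slc39a12 were among those higher with both, and Retnla, Irf4, Cxcl10, Rgs2, Kcnn4 and Flt1 among those lower with both. Of the 1360 genes that moved the same way, 211 (15.5%) differed between the agents, such as Fkbp5. Psrc1, Zmat3, Plau and Cdkn1a rose with nutlin-3a and fell with 10058F4, while Angptl4, an inhibitor of lipoprotein lipase, fell with nutlin-3a (-0.88, SE 0.14) and rose with 10058F4 (0.99, SE 0.14). Plau, Angptl4, Flt1, Rgs2 and Kcnn4 were named here after their values were seen.

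Independent lists of these sizes would share 139.2 genes higher and 82.06 lower, with 219.2 opposite. The log2 differences correlated with r = 0.66 across genes, which are not independent replicates. Unchanged groups simulated against the same M2 arrays, without correlated replicate numbers, averaged 0.502 (0.441 to 0.57), so set no bound. The covariance was 0.0574 against 0.00721. The 3 M2 arrays are too few to split, so part of the excess of shared genes over independent lists may come from shared controls. Leaving out 1 array gave 480 higher with both (M2 replicate 1) or 513 (nutlin-3a replicate 2), 331, 336, 336 or 355 lower (M2 replicates 1 and 3, nutlin-3a replicates 1 and 2) and 14 opposite (M2 replicate 1 or 2). At a change of at least 2-fold, 33 were higher with both, 22 lower and 0 opposite.

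**Figure D3:**
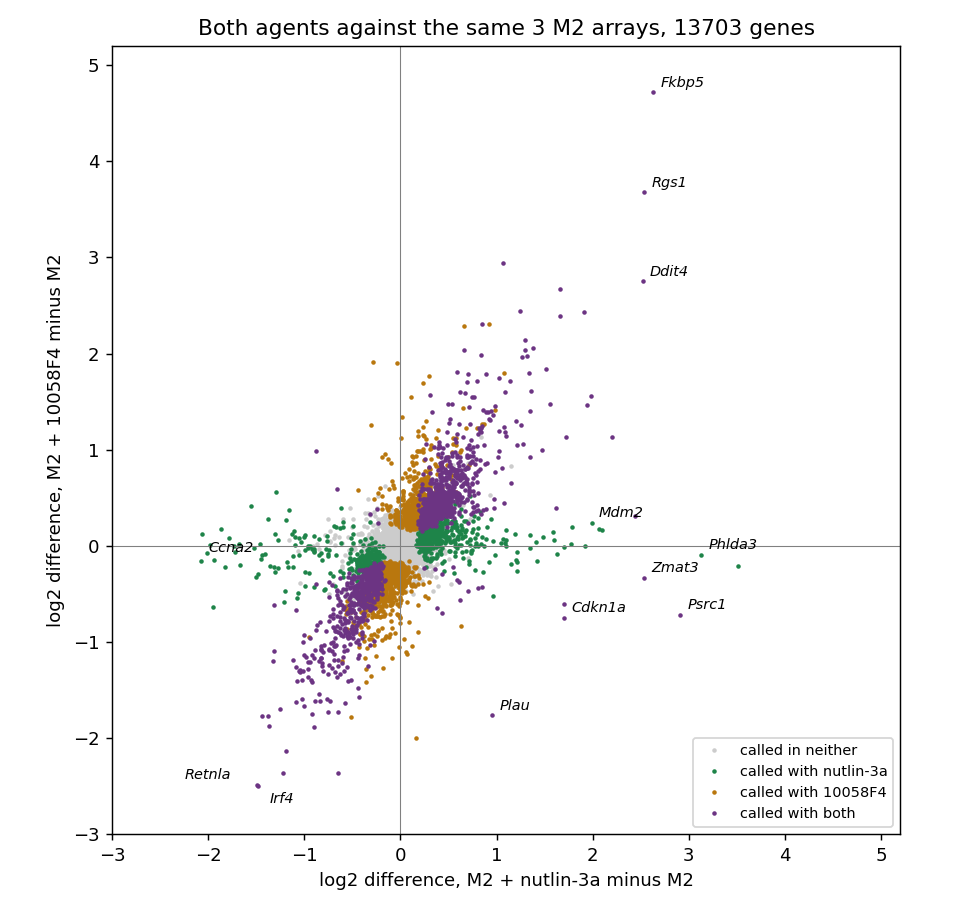
Log2 difference from M2 cells with nutlin-3a (x axis) and with 10058F4 (y axis) of 13703 genes (points), coloured by which agent's limma test called them. Of the genes called with both, 815 lie in the upper right, 545 in the lower left and 22 in the other quadrants, and Phlda3 and Mdm2 lie near 0 on the y axis.

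The 200 genes raised at least 2-fold in M2 over M0 cells were followed under each agent. With nutlin-3a 48 of them were lower and 21 higher than in M2 cells, and with 10058F4 94 were lower and 24 higher. Irf4, Retnla and F2r were among those lower with 10058F4. The median log2 difference was -0.091 with nutlin-3a and -0.29 with 10058F4, with SDs of 0.028 and 0.046 over replicate numbers, and a median of 94.3% and 80.6% of the rise remained. Of the 219 genes lowered at least 2-fold in M2 cells, 30 were lower and 51 higher with nutlin-3a (median 0.11) and 29 lower and 74 higher with 10058F4 (median 0.20).

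These directions depended on how the genes were chosen. Choosing them from the other agent's arrays against M0, without the M2 arrays, reversed all 4 medians: 0.31 for 241 induced genes (10 lower, 100 higher) and -0.25 for 298 repressed genes (105 lower, 10 higher) with nutlin-3a, and 0.058 for 282 induced genes (59 lower, 91 higher) and -0.14 for 304 repressed genes (85 lower, 25 higher) with 10058F4. That choice takes in genes moved by the other agent, and the agents' differences covary. Choosing the genes with 1 M2 array and measuring against the other 2, chosen after seeing the data, kept the directions, with medians of -0.086, -0.059 and -0.055 for induced genes with nutlin-3a and of -0.30, -0.26 and -0.26 with 10058F4. The bootstrap intervals of these medians over genes lay below 0 with 10058F4 (at most -0.109) and reached 0.007 with nutlin-3a. Such intervals hold no spread between arrays.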

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

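The tests of shared M2 noise, of an equal shift in both arms, of the glucocorticoid list in each arm and of genes chosen on 1 M2 array were chosen after the results were seen.

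Against the same M2 arrays 22 genes were called opposite ways, given as nutlin-3a minus 10058F4 (a difference that follows from this choice) and chosen after their values were seen where outside the rule for named genes. Higher with nutlin-3a were Psrc1 (3.63), Zmat3 (2.87), Plau (2.71), Cdkn1a (2.45), Ak1 (2.31), Thyn1 (1.28), Dcxr (1.24), Orai2 (1.18), Susd6 (1.18), Btg2 (1.13), Neat1 (1.04), Flrt3 (0.99), Lacc1 (0.94), Cdc34 (0.77), Snx20 (0.73), Rab40c (0.60) and Rrp36 (0.47). Lower were Angptl4 (-1.87), Abcd2 (-1.26), Ppp1r13b (-0.65), Mrtfa (-0.63) and Casp8 (-0.48). By list, camera's direct test called p53 targets (median 1.087), cholesterol synthesis (0.358), M1 markers (0.203), ATF4 genes (0.203), MHC class I (0.184) and oxidative phosphorylation (0.107) higher with nutlin-3a, and mitosis (-1.103), DNA replication (-0.248) and the unfolded protein response (-0.065) lower. With an estimated correlation only the p53 call held, and the others had adjusted p from 0.14 to 0.554.

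Of 9 genes known to be raised by glucocorticoids (Fkbp5, Tsc22d3, Per1, Dusp1, Ddit4, Mertk, Sgk1, Klf9 and Zbtb16, picked for their rises), 7 were called higher with nutlin-3a (median 1.24; Klf9 at 0.39 and Zbtb16 at 0.03 were not called) and 9 with 10058F4 (median 2.39). Noise of the shared M2 arrays is argued against by rises over M0 as well, with the smaller median at 1.05. An equal vehicle or handling shift as the whole cause is argued against by the median direct difference, -0.817, with 7 of 9 genes called. Because the genes were picked for their rises, part of that difference may follow from the choice. Both points cover these 9 genes only. A list of 26 other glucocorticoid-raised genes, written before their values were looked at, was to be called with both agents; the larger camera p was 0.17, for nutlin-3a, and that p and the median of 0.0196 each met the bound written beforehand against the explanation (p of 0.05 or more, or a median under 0.1). The bootstrap interval of that median, -0.06 to 0.29, reaches above 0.1, so the joint explanation stays open; the agents were judged apart only afterwards, and with 10058F4 the list was higher (median 0.13, p = 0.00257, 0.0162 with an estimated correlation; 10 of 26 called higher and 1 lower), as the rule written afterwards asked, though its interval, -0.01 to 0.47, includes 0, so this stays open too. Unequal vehicle amounts stay open and untested, as does an effect of p53 or MYC on these genes.

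Of 200 genes raised at least 2-fold in M2 cells, 48 were lower with nutlin-3a and 94 with 10058F4. The count in simulated unchanged arms (at most 1 called lower) decides nothing about regression to the mean, since such arms give almost no calls; their medians (-0.037 to 0.019 and -0.038 to 0.013) lay above the observed -0.091 and -0.293, but with noise drawn separately for each gene. With genes chosen on 1 M2 array and measured against the other 2, the median's bootstrap intervals reached at most -0.109 (10058F4) and 0.007 (nutlin-3a). They hold no spread between arrays, so noise of single M2 arrays stays open. The 200 genes' medians lay below those of all 10000 matched lists (lowest -0.037 with nutlin-3a and -0.068 with 10058F4). RMA hides an equal fall of all genes, so this cannot test one. Choosing genes from the other agent's arrays reversed the medians (0.306 and 0.058), perhaps through the agents' covarying effects, and a weaker response to IL-4 and IL-13 stays open.

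More genes fell than rose by 2-fold in M1 cells (1737 against 783, a ratio of 2.22), and with repeated quantile normalization (1391 against 920), but not with arrays centred on their median (1066 against 1252), which shifts all genes alike. Low quality of M1 replicate 2 is argued against by a ratio of 2.36 without it. The spiked control probe sets had a median difference of -0.095 between M1 and M0, which passes part of the bound written against a downward shift by the normalization. That bound was wrong, because the controls went both ways: hybridization controls were at a median of 0.233 and poly-A controls of -0.378, lower for 23 of 24 (but -0.318 in M2 against M0, with 219 falls and 200 rises, so not particular to M1). A shift by the normalization and a response to LPS and interferon-gamma therefore cannot be told apart.

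As to other groupings of the arrays, 10 splits of 6 arrays are too few for a share under 0.05. The real splits called 9963 (M1 and M0), 4253 (M2 and M0), 8860 (M1 and M2), 2112 (nutlin-3a and M2), 2858 (10058F4 and M2) and 954 genes (both agents), each 1 of 10 splits with as many, and the highest of the others called 0, 1, 0, 0, 1 and 0.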

How the results depend on the processing

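The choice of genes with 1 M2 array and measurement with the other 2 was added after seeing the data; the others were planned. Over the other settings, the 616 results on named genes were the same 9281 times, lost their call 430 times, gained one 71 times and reversed 3 times. The lists, 154 results beside those below, were the same 1723 times, lost their call 95 times and gained one 24 times. The cause was not tested unless given.

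Reversed were Pdgfrb in M1 against M0 (-0.409 with the mean of all probe sets), Tap1 in M2 against M0 (0.09, same setting) and H2-DMb2 in M1 against M0 (0.025 with arrays centred). A stricter filter gave 2962 genes higher in M1 than M0, since fewer genes were tested. Centring gave 7619 higher and 3505 lower in M1 against M0 (1252 and 1066 by 2-fold), 2801 higher in M2 against M0, 6896 higher in M1 against M2 and 1320 lower with nutlin-3a. Array weights gave 2022 higher and 1280 lower with nutlin-3a, 2201 and 2110 with 10058F4, and 1272 and 772 between the agents, where the 6 arrays alone gave 875 and 608. With an estimated correlation 2 of 15 lists stayed called in M1 against M0, 1 of 8 in M2 against M0, 3 of 17 in M1 against M2, 2 of 10 with nutlin-3a, 0 of 9 with 10058F4 and 1 of 9 between the agents. Mitosis with nutlin-3a (median -1.105) then had an adjusted p of 0.322 (4.66e-16 to 1.17e-10 with arrays left out).

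Calls of at least 2-fold left 33 genes higher with both agents, 22 lower and 0 opposite. Genes chosen from the other agent's arrays gave, for M2-induced genes, 10 lower and 100 higher with nutlin-3a (median 0.306) and 59 and 91 with 10058F4 (0.058), and for repressed genes 105 and 10 (-0.246) and 85 and 25 (-0.144); this choice takes in genes the other agent moved. With a change of log2 2 or more, induced genes gave 12 lower and 6 higher with nutlin-3a (-0.146) and 24 and 5 with 10058F4 (-0.378), and repressed genes 2 and 0 (0.155) and 1 and 3 (0.265), with fewer genes. Chosen with 1 M2 array, induced genes had medians of -0.059 and -0.055 with nutlin-3a, and repressed genes of 0.036 with nutlin-3a and 0.1 with 10058F4, for M2 arrays 2 and 3 as far as they moved by over 1 SD.

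Leaving out 1 array at a time gave 756 to 980 higher and 462 to 579 lower with nutlin-3a, 339 to 464 and 213 to 258 between the agents, and 480 to 679 higher, 331 to 424 lower and 14 to 19 opposite with both agents. M2 markers with nutlin-3a had medians of -0.206 to -0.09 (adjusted p 0.0228 to 0.0876). Induced genes higher with nutlin-3a numbered 13 to 23 and repressed genes lower 17 to 37; repressed medians were 0.086 to 0.146 with nutlin-3a and 0.158 to 0.223 with 10058F4. Fewer arrays give less power, which lowers counts of calls.

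The replicate block gave 4729 higher and 5461 lower in M1 against M0, 1914 and 2732 in M2 against M0, 3996 and 5121 in M1 against M2, 1532 and 1013 with nutlin-3a, 1632 and 1611 with 10058F4 and 742 and 490 between the agents. Replicate numbers do not pair M1 arrays with M0 (r of 0.06 to 0.26) or M2 arrays (0.06 to 0.15), though each array correlated best with its own number, a hint from the data. Among named genes the block gained or lost calls of Mdm2, Cd209a, Postn and Cenpa in M2 against M0, Cd3d, Postn, Slc7a11 and Dld with nutlin-3a, Cd3d, Mki67 and Gins1 with 10058F4, Batf3, Acadl and H2-DMa between the agents, and Klf1 and Il2rb in comparisons with M1; among lists, dendritic cell markers with nutlin-3a and MHC class II with 10058F4. It changed no other call. Signal over background is not known per probe set, so small changes of dim genes are limited by the filter.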

Other observations

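Values against M0 cells, which the comparisons of the agents leave out, were looked at only after the results were seen. With 10058F4, Fkbp5 was 5.55 (SE 0.15) above M0 and Klf9, a transcription factor raised by glucocorticoids, 2.71 (SE 0.14); with nutlin-3a they were 3.46 and 1.89 above M0. Mertk was 0.72 (SE 0.09, adjusted p = 3.4e-05) above M0 with 10058F4 and at -0.13 (adjusted p = 0.33) with nutlin-3a, while M2 cells were at -1.43 against M0. The list of 26 other glucocorticoid-raised genes had medians of 0.335 (camera p = 0.00903, 0.0314 with an estimated correlation) with nutlin-3a and 0.389 (p = 0.000393, 0.00682) with 10058F4 against M0, a comparison that also holds the effect of IL-4 and IL-13.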
